A study of Mus musculus with 770 samples.

How the data were processed

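Lung innate lymphoid cells (ILCs) of C57BL/6 mice were profiled in 770 samples: 18 droplet libraries (10x, 3' tags, UMI counts) and 752 wells of full-length SMART-Seq2 plates. The sort gate was live CD45+, lineage-negative, CD90.2+ and CD127+. The 3-day set held 10 droplet libraries of PBS, IL-25, IL-33, NMU and NMU+IL-25, each given daily on 3 consecutive days. The house dust mite (HDM) set held 8 droplet libraries of wildtype and Nmur1 knockout mice dosed with PBS or HDM on days 0, 7, 8 and 9. Each group had 2 libraries, and each library was a pool of lungs of mice of a treatment group, per the series description; the number of mice per pool was not used here. Plates held 188 and 94 wells of PBS, 94 and 94 of IL-25, and 188 and 94 of IL-33, for replicates 1 and 2.

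The deposited droplet matrices held counts of UMIs per gene and cell, per the labels' library protocol, and were listed with Cell Ranger 1.3.1 and the mm10 genome build in the submitters' processing notes. The deposited plate tables held expected counts and TPM per gene and well, per the file headers and the submitters' processing notes, which named RSEM 1.2.8 with Bowtie. The notes also named kallisto 0.42.3 without saying which file it made. Of the nonzero plate counts, 34.04% were not whole, and the plate tables listed 20572 genes and 0 mitochondrial genes. The TPM table had 2 sample columns that no label listed, and these were not used. Of 27998 gene IDs in the droplet matrices, 27645 (98.7%) were found in GENCODE M21, which was used only for gene positions.

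Droplets with at least 500 genes and at most 10% mitochondrial UMIs were kept, 73811 cells in all. Wells with at least 500 genes were kept, 721 of 752, and 31 were removed. Counts were summed over the cells of each library, because cells of a pool are not replicates; expected counts were summed over the plates of a replicate and then rounded. Summed UMIs ran from 4563045 in the smaller knockout PBS library to 62364527 in an NMU+IL-25 library.

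Each contrast was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, filterByExpr, TMM scaling, 2-sided, Benjamini-Hochberg adjustment) in R 4.3.3. Libraries of a set were fitted together: 13205 genes in the 3-day set, 12674 in the HDM set and 13117 in the plates, with common dispersions of 0.0111, 0.0257 and 0.84. A gene was called at an adjusted p under 0.05, and rose, fell and changed are used of called genes only. Where a droplet group had 0 counts, the fold is a floor that takes 3 counts over that group, and where it had few counts the fold is the pooled ratio with a 95% counting interval. Intervals and floors cover counting error only, whereas p-values measure the spread between these pools. The 17 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), again with a correlation estimated from the residuals, and with fry, and adjusted over the lists of a contrast. Members of a list were also counted after adjustment over the list alone. Lists, contrasts, tests and the rule for named genes were fixed before the data were examined.

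Genes were named by rule. In each contrast up to 8 rising and 8 falling genes with the largest log2 fold changes were taken from genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 20 CPM and libraries of the groups that did not overlap (the last not asked of interactions), leaving out predicted, Rik, mitochondrial and ribosomal protein genes. Up to 4 members of each list with the smallest p were added, and Nmur1, Il5, Il13, Areg, Il17rb, Il1rl1, Klrg1, Gata3, Calca and Mki67 were always reported. A gene outside the rule is marked in the text as chosen after the values were seen.

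Cells were clustered with scanpy 1.11.5 (10000 counts per cell, 2000 highly variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 7), which gave 20 clusters. A cluster took a class name from at least 3 fixed markers detected in at least 10% of cells. Save for ILC2 markers, they lay at least 2-fold above other clusters after adding 10 CPM. Class names are rebuilt here, not the study's. Shares of cells were counted after thinning each cell to 1000 UMIs. A cell counted as cycling with UMIs of at least 3 of 94 listed S and G2/M phase genes, and a second measure, added after seeing the data, asked for at least 2 of 10 mitotic genes. Shares were not tested, because an exact permutation test of 2 libraries against 2 cannot fall below 0.333.

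Alternatives were DESeq2 1.42.0, library totals without TMM, no expression filter, replicate number as a block, each library left out in turn, totals thinned to the smallest, stricter cells (1000 genes, 5% mitochondrial), ILC2-like clusters only, limma on log2 mean TPM (pseudocounts 1 and 0.1), thinning to 1500 UMIs or not at all, and 3000 variable genes or resolution 2 for the clusters. Chosen after seeing the data were leaving out clusters with markers of other cell types, the mitotic measure, and the receptor list without Nmur1. Scrublet's automatic threshold marked 12 of 73811 cells (0.0163%), so the cells with the highest scores were left out instead, at 0.8% per 1000 cells of a library (2576 cells, 3.49%). Replicates were checked and none was deposited more than once.

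Each test was tried on simulated counts with known changes. In simulated IL-25 data edgeR found 38.5% of 1.5-fold, 65.1% of 2-fold and 93.5% of 4-fold changes, with 5 false calls of 149. For the interaction of NMU and IL-25 these shares were 13.4%, 60.0% and 83.1%, for HDM in wildtype 9.2%, 56.1% and 90.9%, and for genotype by HDM 6.0%, 14.3% and 66.7%. On simulated plates edgeR found 0%, 0% and 1.6%, while DESeq2 made 204 calls, 160 (78.4%) false. Only the changed list was called each time, but genes were drawn independently.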

Results

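Transcript counts were measured in single lung ILCs of C57BL/6 mice after intranasal PBS, NMU, IL-25, both together (NMU+IL-25), or IL-33, and of wildtype and Nmur1 knockout mice after PBS or house dust mite extract (HDM). Each droplet group had 2 libraries, and PBS, IL-25 and IL-33 were also sequenced as full-length SMART-Seq2 plates with 2 replicates each. Depth differed between treatments. Summed UMIs were 15998745 and 14322258 after PBS, 24964329 and 20514701 after IL-25, 53804216 and 61351973 after IL-33, 20428915 and 16742629 after NMU, and 62364527 and 56632795 after NMU+IL-25. The HDM set held 16544773 and 15496104 UMIs in wildtype PBS, 17893253 and 22242630 in wildtype HDM, 4563045 and 20455759 in knockout PBS, and 19433129 and 22379165 in knockout HDM. Median UMIs per cell were 2542 and 2658 after PBS against 13251 and 12854 after IL-33. Levels and fold changes are relative to the scaled total of a library. A fall after IL-33 or NMU+IL-25 therefore does not show fewer transcripts per cell. Plates kept 721 cells, and expected counts summed to 76660263 and 87754992 (PBS), 84428938 and 93232179 (IL-25), and 90971637 and 111355414 (IL-33).

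Clusters with ILC2 markers held most sorted cells in every droplet library. Their share was 89.5% and 90.1% after PBS, 76.2% and 75.0% after IL-25, 86.5% and 88.1% after IL-33, 88.2% and 88.1% after NMU, and 79.3% and 72.5% after NMU+IL-25. In the HDM set it was 88.9% and 88.9% in wildtype PBS, 77% and 84.6% in wildtype HDM, 80.9% and 85.1% in knockout PBS, and 71.2% and 57.1% in knockout HDM. The second knockout HDM library also held T cell-like (15.2%), mixed T and NK (8.9%), ILC1 or NK-like (6.0%) and macrophage-like (3.6%) cells. Clusters left unnamed held 2.32% and 1.16% of PBS cells, 13.4% and 12.3% after IL-25, 10.7% and 9.6% after IL-33, 2.73% and 4.26% after NMU, and 18.2% and 22.0% after NMU+IL-25. In the HDM set unnamed clusters held 1.17% and 4.78% (wildtype PBS), 3.87% and 4.03% (wildtype HDM), 1.79% and 2.4% (knockout PBS), and 3.8% and 7.99% (knockout HDM). The largest unnamed cluster carried Gzma, Gzmb, Il6 and Il4, and another carried Ccr10 and MHC class II genes. Sftpc, an epithelial gene, and Hba-a1, an erythroid gene, were among the genes that told clusters apart, and both belong to cell types outside the sort gate.

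**Figure D1:**
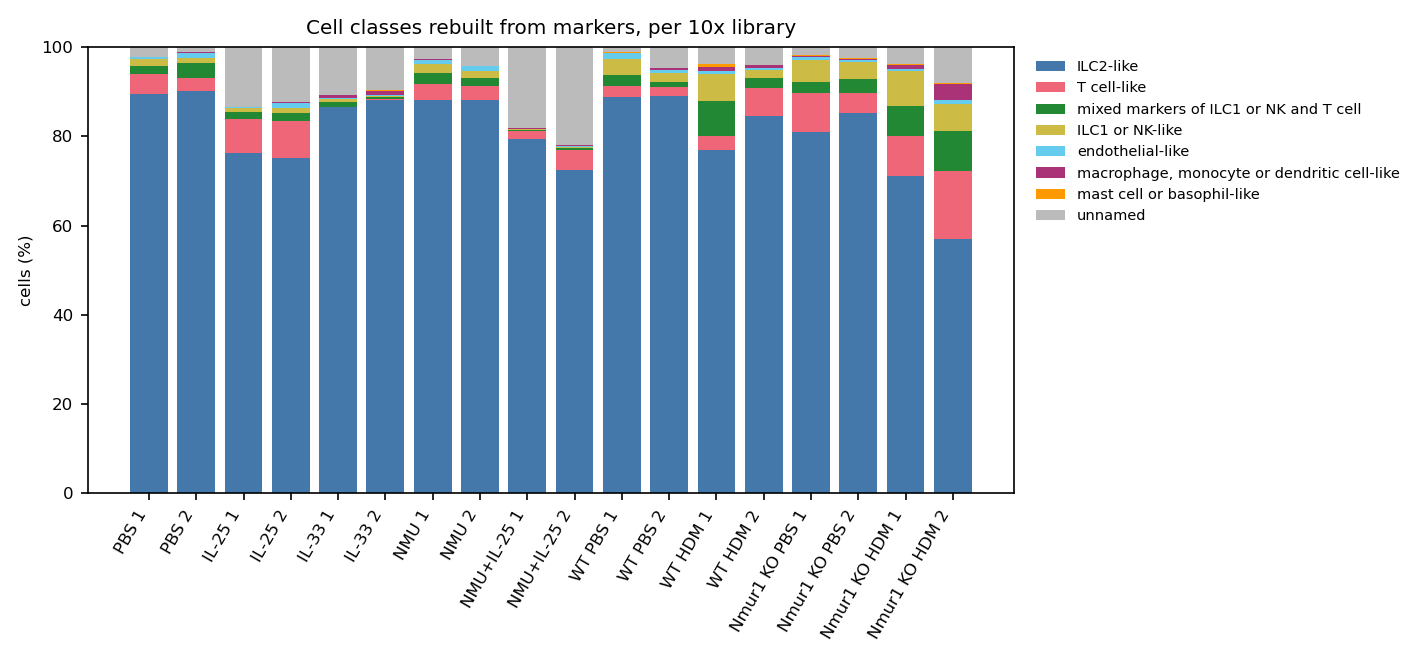
Percent of cells per cluster class in each of the 18 droplet libraries. ILC2-like cells ranged from 57.1% in the second knockout HDM library to 90.1% in the second PBS library.

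The first comparison asked what 3 days of IL-25 changed in the sorted ILCs. Il13, which encodes a type 2 effector cytokine, rose from 23 to 824 CPM (n = 2 libraries per group; log2 fold change 5.16, adjusted p = 3.2e-06). Il5 rose by 2.53, Il6 by 4.93, Il4 by 1.91 and Areg by 0.96 on the log2 scale (adjusted p = 0.00023, 5.37e-06, 0.000186 and 0.00194). Tph1, whose product starts serotonin synthesis, rose by 5.60, the triglyceride enzyme gene Dgat2 by 5.04 and the checkpoint gene Ctla4 by 4.51 (adjusted p = 1.01e-07, 1.48e-06 and 1.97e-07). Il1r2, a decoy receptor for IL-1, rose by 7.80 from 0.309 CPM. PBS libraries held only a few UMIs of Tff1 and Asic3, which stood at 45.3 and 39.9 CPM after IL-25 against 0.0337 and 0.0971 CPM (adjusted p = 5.6e-05 and 1.06e-05).

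Igfbp4 (-2.08), the Notch target Hes1 (-1.89), Metrnl (-1.66), Pard3 (-1.62), Klf5 (-1.60), Socs2 (-1.60), Bambi (-1.56) and Socs1 (-1.55) fell most after IL-25 (largest adjusted p = 8.74e-05). Klrg1 rose by 1.29 (adjusted p = 0.000145) and Calca by 1.04 (adjusted p = 0.00149), while Gata3 fell by 0.60 (adjusted p = 0.00024). Il1rl1 (-0.29), Il17rb (0.20) and Nmur1 (0.32) were not called (adjusted p = 0.088, 0.12 and 0.289). Nmur1 stood at 53.5 and 50.8 CPM after IL-25 against 35 and 48.4 CPM after PBS.

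Type 2 cytokines and effector molecules moved as a group after IL-25: 10 of 16 rose and 1 fell (median log2 fold change 1.40; camera adjusted p = 3.12e-10; adjusted p = 0.0675 with an estimated correlation). Of S phase genes 37 of 42 rose (Uhrf1 3.01, Gins2 2.45, Rad51 2.80), and of G2/M phase genes 45 of 52 (Mki67 3.56, Cks1b 2.93, Ccnb2 3.64), with none falling in either list (adjusted p = 0.074 and 0.0675 with an estimated correlation). Activation and checkpoint receptors rose in 12 of 20 and fell in 3 (Pdcd1 1.64, Tnfrsf1b 1.34; adjusted p = 0.0548 with an estimated correlation). Among genes of the unfolded protein response and secretion 20 of 23 rose (Sdf2l1 1.26, Manf 0.99), of the proteasome 18 of 20 (Psmb7 0.89), of oxidative phosphorylation 30 of 33 (Cox5a 0.74), and of ribosome biogenesis 16 of 25 (Nhp2 1.04, Npm1 0.68). Camera called these 4 lists up, but the calls were lost with an estimated correlation (adjusted p = 0.200, 0.182, 0.285 and 0.285).

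Immediate early genes went the other way, with 15 of 23 falling and none rising (Btg2 -1.44, Junb -1.17, Ier2 -1.02; adjusted p = 0.0548 with an estimated correlation). Lipid uptake and storage genes rose in 9 of 20 (Fabp5 2.71, Dgat1 1.21), and glycolysis genes rose in 7 of 16 and fell in 2 (Tpi1 1.03, Pkm 0.74, Gpi1 0.42; adjusted p = 0.130 and 0.376 with an estimated correlation). Interferon response genes rose in 9 of 26 and fell in 1 (Gbp3 1.96, Ifi27l2a 1.62; adjusted p = 0.514 with an estimated correlation). ILC2 identity genes fell in 7 of 15 (Bcl11b -0.53, Ets1 -0.32), and receptors for neuropeptides and neurotransmitters fell in 5 of 12 with 1 rising (Adrb2 -1.03, Ptgir -0.62, Ramp1 -0.41; adjusted p = 0.359 and 0.117 with an estimated correlation). The inflammatory ILC2 list rose in 4 of 12 and fell in 2 (Batf 2.32, Irf4 2.96, Ly6c2 -1.13; adjusted p = 0.117 with an estimated correlation). Within ILC2-like clusters alone Ly6c2 instead stood higher by 0.90 and was not called (adjusted p = 0.109). NF-kB targets rose in 4 of 18 and fell in 4 (Icam1 0.73, Rel 0.89, Ltb -0.70, Tnfaip3 -0.75), and trafficking receptors rose in 3 of 20 and fell in 3 (Ccr4 1.18, Ccr2 -0.88, Sell -1.55). Camera called neither list (adjusted p = 0.794 and 0.655), and the median of NF-kB targets (0.01) had the opposite sign to the test.

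In the IL-25 comparison edgeR called 4545 of 13205 genes, 2625 up and 1920 down. Without the second IL-25 library the count was 2989, with the lone library assumed to vary like the others. Of 11 ILC2 markers 3 rose and 3 fell, of 12 ILC1 or NK markers 2 rose and 2 fell, of 13 macrophage, monocyte or dendritic cell markers 3 rose, and of 4 mast cell or basophil markers 2 rose.
The second comparison asked the same of IL-33. Il13 rose by 5.14 on the log2 scale (23 to 812 CPM), Il6 by 4.73 and Il5 by 2.29 (adjusted p = 2.75e-07, 5.18e-07 and 8.22e-05), whereas Areg fell by 0.54 (adjusted p = 0.0159, and 0.107 and 0.129 without the second PBS or the second IL-33 library). Il1r2 rose by 9.00, Msc, which encodes a transcriptional repressor, by 7.70, AA467197 by 5.76, Slc15a3 by 5.57, Plac8 by 5.44 and Ccnb2 by 5.35 (largest adjusted p = 5.34e-07). Tff1, of which PBS libraries held only a few UMIs, rose at a pooled ratio of 7940-fold (95% counting interval 1430 to 314000), and Tnfrsf8 stood at 60.2 CPM against 0.0297 CPM (adjusted p = 9.88e-07 and 7.2e-08). Nmur1 fell from 41.7 ± 9.47 to 10.7 ± 1.29 CPM (SD, n = 2; log2 fold change -1.97, adjusted p = 4.99e-05). Lpcat2 (-4.23), the clock gene Dbp (-4.22), Bmp2 (-4.12), the cytokine gene Il2 (-4.08), Pard3 (-3.41), Vwa1 (-3.33) and Frmd4a (-3.31) also fell (largest adjusted p = 7.73e-05). Sftpc, a marker of epithelial cells, fell by 7.72 (adjusted p = 0.0278).

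Klrg1 rose by 0.92 and Il17rb by 0.62 after IL-33 (adjusted p = 0.000233 and 0.000238), Gata3 fell by 1.18 and Il1rl1, the IL-33 receptor gene, by 1.21 (adjusted p = 7.31e-07 and 1.76e-05), and Calca (0.28) was not called (adjusted p = 0.173). Immediate early genes fell in 18 of 23 and rose in 2 (Btg2 -3.08, Zfp36 -2.60, Junb -2.46, Nr4a1 -2.19), the list whose call was kept (adjusted p = 0.0226 with an estimated correlation). S phase genes rose in 41 of 42 (Gins2 4.31, Clspn 4.01, Tipin 2.35) and G2/M phase genes in 50 of 52 (Mki67 4.63, Cks1b 4.59, Cenpa 3.78), with adjusted p = 0.0871 for each with an estimated correlation. The receptor list fell in 10 of 12 and rose in 1 (Adrb2 -2.30, Cnr2 -1.78, Ptgir -1.42, Ramp3 -1.25; adjusted p = 0.0871 with an estimated correlation). ILC2 identity genes fell in 11 of 15 and rose in 3 (Il7r -1.97, Icos -1.65, Ets1 -1.12; adjusted p = 0.187 with an estimated correlation).

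All 20 proteasome genes rose after IL-33 (Psmb7 1.54, Psma4 1.24), as did 32 of 33 oxidative phosphorylation genes (Cox5a 1.58), 24 of 25 ribosome biogenesis genes (Nhp2 1.89, Npm1 1.41) and 21 of 23 genes of the unfolded protein response and secretion (Sdf2l1 1.97, Manf 1.56). With an estimated correlation these camera calls were lost (adjusted p = 0.187, 0.224, 0.206 and 0.224). Interferon response genes rose in 21 of 26 and fell in 1 (Gbp3 3.07, Ifi27l2a 2.90, Bst2 1.79), glycolysis genes rose in 11 of 16 and fell in 2 (Pgam1 2.18, Tpi1 2.10), and lipid genes rose in 12 of 20 and fell in 2 (Fabp5 4.55, Dgat2 2.10, Scd2 1.93; adjusted p = 0.289, 0.256 and 0.187 with an estimated correlation). Activation and checkpoint receptors rose in 11 of 20 and fell in 6 (Ctla4 4.29, Il2rb 1.11, Cd200r1 -1.25), and type 2 cytokines rose in 7 of 16 and fell in 3 (Tnfsf8 2.14; adjusted p = 0.187 and 0.318 with an estimated correlation). NF-kB targets fell in 10 of 18 and rose in 3 (Nfkbiz -1.99, Tnfaip3 -1.99, Ltb -1.63), and trafficking receptors fell in 12 of 20 and rose in 4 (Sell -2.79, Ccr2 -1.63, Cxcr6 -0.88; adjusted p = 0.267 and 0.321 with an estimated correlation). The inflammatory ILC2 list rose in 4 of 12 and fell in 5 (Irf4 4.24, Batf 1.99, Ly6c2 -2.27, Rorc -1.46; camera adjusted p = 0.627), and its median (-0.20) and mean (-0.24) had the opposite sign to the test. Within ILC2-like clusters alone Ly6c2 rose by 0.97 instead (adjusted p = 0.0388).

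In the IL-33 comparison edgeR called 8811 genes, 4224 up and 4587 down, and 7357 to 7866 with any single library left out. Markers of other cells went both ways: 6 of 7 T cell, 6 of 12 ILC1 or NK, 6 of 9 ILC3, 6 of 8 epithelial and 5 of 7 endothelial markers fell. In contrast, 5 of 13 macrophage, monocyte or dendritic cell markers rose and none fell. B cell markers rose in 2 of 5 and fell in 2, and mast cell or basophil markers rose in 2 of 4 and fell in 1. The median log2 fold change of all tested genes was -0.08, and -0.29 when libraries were scaled by their totals alone.
NMU alone was compared with PBS to find what the neuropeptide changed without IL-25. The checkpoint gene Pdcd1 rose by 1.57 on the log2 scale (adjusted p = 0.000886), as did Cd63 (1.64), Prnp (1.33), Anxa2 (1.29), Serpinb6a (1.17) and Tubb6 (1.14; largest adjusted p = 0.0483). Il5 rose by 1.31 from 47.5 CPM (adjusted p = 0.0376) and Il13 from 23 to 50.5 CPM (1.13, adjusted p = 0.0316). Igfbp4 (-1.28), Il2 (-1.27), Lmo4 (-1.12), Enpp4 (-1.06), Hs3st1 (-1.03) and Frmd4a (-1.01) fell (largest adjusted p = 0.00737). Hba-a1, an erythroid marker with a near-identical copy whose reads could not be told apart, fell by 1.70, and 2 of 4 erythroid or platelet markers fell with it. Nmur1 itself fell from 41.7 to 21.1 CPM (log2 fold change -0.99, adjusted p = 0.0461). Klrg1 rose by 0.82, Mki67 rose by 1.18, Calca fell by 0.80 and Il17rb fell by 0.48 (adjusted p = 0.0152, 0.00737, 0.0361 and 0.0286), while Areg (-0.26), Gata3 (-0.22) and Il1rl1 (-0.27) were not called (adjusted p = 0.427, 0.124 and 0.253). Calls in this comparison hung on single libraries. Without the second PBS library those of Nmur1, Calca, Il17rb, Il13, Il5 and Mki67 were lost (adjusted p = 0.186, 0.151, 0.112, 0.152, 0.165 and 0.07). Without the first PBS library those of the first 5 and Klrg1 were lost (0.0568 to 0.145). Without the first NMU library those of Nmur1, Calca and Il17rb were lost (0.123 to 0.167), and without the second those of Klrg1 and Il13 (0.0645 and 0.0576).

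Activation and checkpoint receptors moved as a group after NMU, with 7 of 20 rising and 2 falling (Tnfrsf4 3.38, Tnfrsf9 1.33, Il2rb 0.62; camera adjusted p = 1.19e-06), and the call was kept (adjusted p = 0.046 with an estimated correlation). G2/M phase genes rose in 11 of 52 and fell in 2 (Hmmr 1.48, Kif23 -0.82; adjusted p = 0.479 with an estimated correlation), whereas S phase genes rose in 1 of 42 and fell in 1 (Uhrf1 0.74, Chaf1b -0.54; camera adjusted p = 0.337). ILC2 identity genes fell in 4 of 15 and rose in 1 (Icos -0.70, Il2ra -0.50, Crlf2 0.39), ribosome biogenesis genes fell in 3 of 25 (Ppan -0.57, Gnl3 -0.49), and immediate early genes rose in 2 of 23 and fell in 2 (Egr2 1.54, Ier3 1.24, Fos -0.51). Camera called these 3 lists down, and the calls were lost (adjusted p = 0.435 for each with an estimated correlation). Oxidative phosphorylation was called down by camera with 0 of 33 members called (adjusted p = 0.015; adjusted p = 0.913 with an estimated correlation). Type 2 cytokines rose in 4 of 16 and fell in 3 (Tnfsf8 1.13, Penk 4.16), and the inflammatory ILC2 list rose in 2 of 12 and fell in 1 (Irf4 2.58). No other list was called, and among its members Dgat2 rose by 1.60, Hk2 fell by 1.11, Itgae rose by 1.40, Ccr7 fell by 0.92, Traf1 rose by 0.57, Ramp1 rose by 0.50 and Adrb2 fell by 0.64. Within ILC2-like clusters alone Ccr7 stood higher after NMU by 0.56 instead and was not called (adjusted p = 0.193).

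After NMU edgeR called 545 of 13205 genes (4.13%), 64% of them up. With a library left out, and the lone library assumed to vary like the others, the share called was 0.795% without the second PBS library, 1.21% without the first, 1.26% without the first NMU library and 2.11% without the second. Scaled by library totals alone the count was 836, of which 85.6% were up.
NMU given with IL-25 was compared with PBS next. Ctla4 rose by 5.73 on the log2 scale, Tox2 by 5.55, Msc by 8.73 and Il1r2 by 8.87 (largest adjusted p = 6.5e-07). Gzma and Gzmb, granzyme genes that also mark NK cells, rose by 7.20 and 5.62 (adjusted p = 0.000158 and 0.000294), although 8 of 12 ILC1 or NK markers fell and 2 rose. Tff1 and Tnfrsf8 rose at pooled ratios of 3210-fold (95% counting interval 576 to 127000) and 2730-fold (490.0 to 108000). Il13 rose from 23 to 828 CPM (5.17), Il6 by 4.32 and Il5 by 2.34 (adjusted p = 2.87e-07, 8.96e-07 and 7.56e-05), whereas Csf2 fell by 3.53 and Areg fell by 0.74 (adjusted p = 2.32e-05 and 0.00296). Il2 (-4.83), Lpcat2 (-4.25), Dbp (-4.22), Bmp2 (-4.09), Spry2 (-3.77) and Vwa1 (-3.58) fell most, and the epithelial marker Sftpc fell by 7.60 (largest adjusted p = 0.0271).

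Klrg1 rose by 1.62 and Il17rb by 0.41, while Nmur1 fell by 1.49, Gata3 fell by 1.29 and Il1rl1 fell by 1.2 in the combined treatment (largest adjusted p = 0.00322), and Calca (-0.38) was not called (adjusted p = 0.0736). Immediate early genes fell in 19 of 23 and rose in 2 (Btg2 -2.98, Klf4 -2.89, Junb -2.48; adjusted p = 0.047 with an estimated correlation). The receptor list fell in 11 of 12 and rose in 1 (Adrb2 -2.22, Ramp3 -1.55, Ptgir -1.43, Calcrl -0.94; adjusted p = 0.0547 with an estimated correlation). S phase genes rose in 41 of 42 (Uhrf1 4.29, Gins2 3.92), G2/M phase genes in 50 of 52 (Mki67 4.65, Cks1b 4.24), and activation receptors in 12 of 20 with 6 falling (Lag3 4.77, Pdcd1 2.08), each with adjusted p = 0.0865 with an estimated correlation. All 25 ribosome biogenesis genes (Nhp2 2.02, Npm1 1.47) and all 20 proteasome genes (Psmb7 1.29) rose (adjusted p = 0.165 and 0.186 with an estimated correlation).

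Oxidative phosphorylation genes rose in 29 of 33 and fell in 1 (Cox5a 1.44), genes of the unfolded protein response and secretion rose in 21 of 23 and fell in 1 (Sdf2l1 1.94), glycolysis genes rose in 11 of 16 and fell in 3 (Pgam1 2.04), and NF-kB targets fell in 9 of 18 and rose in 5 (Tnf -2.19, Ltb -1.88); adjusted p = 0.284 for each with an estimated correlation. ILC2 identity genes fell in 10 of 15 and rose in 1 (Hes1 -3.01, Hs3st1 -2.33), and lipid genes rose in 12 of 20 and fell in 1 (Fabp5 3.98, Plin2 1.08; adjusted p = 0.183 and 0.243 with an estimated correlation). Camera called no change of type 2 cytokines (8 of 16 up, 3 down, Penk 6.18), inflammatory ILC2 genes (5 of 12 up, 3 down, Irf4 3.97, Ly6c2 -3.70), interferon response genes (14 of 26 up, 3 down, Gbp3 2.63) or trafficking receptors (3 of 20 up, 9 down, Ccr2 -2.35; adjusted p = 0.137, 0.203, 0.0905 and 0.0863). Markers of other cells mostly fell: 6 of 7 T cell, 6 of 9 ILC3, 6 of 8 epithelial, 5 of 7 endothelial and all 4 erythroid or platelet markers. Macrophage, monocyte or dendritic cell markers rose in 3 of 13 and fell in 1. EdgeR called 8869 genes, 4295 up and 4574 down, and 7671 to 8076 with any single library left out.

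NMU+IL-25 was then compared with IL-25 alone to find what NMU added. Csf2, which encodes GM-CSF, fell by 4.14 on the log2 scale, Il2 by 3.65, the chemokine gene Cxcl1 by 3.34, Lpcat2 by 2.79 and the mast cell and progenitor protease gene Cpa3 by 2.70 (largest adjusted p = 7.1e-05). The erythroid marker Hba-a1, whose copies could not be told apart, fell by 2.73 and the epithelial marker Sftpc fell by 7.27 (adjusted p = 2.05e-05 and 0.0447), and an Itgam entry that shares its symbol with a second gene ID fell by 2.66 (adjusted p = 0.00359). Msc rose by 3.41, Gzma by 2.44, AA467197 by 2.42, Car5b and Mt1 by 2.30, Tnfrsf8 by 2.23, Ccr7 by 2.16 and Tnfrsf4 by 2.11 (largest adjusted p = 0.0162). Areg fell by 1.71 (408.4 to 125.3 CPM), Nmur1 by 1.82, Calca by 1.42, Il1rl1 by 0.91 and Gata3 by 0.69, while Mki67 rose by 1.09 (largest adjusted p = 0.00035). The cytokine genes Il13 (828 against 824 CPM; log2 fold change 0.01) and Il5 (-0.19), as well as Klrg1 (0.33) and Il17rb (0.20), were not called (adjusted p = 0.982, 0.591, 0.0704 and 0.0918).

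Immediate early genes fell in 18 of 23 and rose in 1 (Nr4a1 -1.80, Btg2 -1.54, Junb -1.31), and the receptor list fell in 10 of 12 and rose in 1 (Adrb2 -1.19, Vipr2 -0.86, Ptgir -0.81) when NMU was added to IL-25. Both calls were kept (adjusted p = 0.0339 for each with an estimated correlation). G2/M phase genes rose in 49 of 52 (Cenpa 1.32, Cks1b 1.31), S phase genes in 40 of 42 (Gins2 1.47, Tipin 1.14) and ribosome biogenesis genes in 24 of 25 (Nhp2 0.97, Gar1 0.80), while ILC2 identity genes fell in 11 of 15 (Hs3st1 -1.82, Tcf7 -1.48, Il7r -1.43); adjusted p = 0.144 for each with an estimated correlation. NF-kB targets fell in 12 of 18 and rose in 1 (Tnfaip3 -1.31, Ltb -1.19), type 2 cytokines fell in 9 of 16 and rose in 2, and trafficking receptors fell in 10 of 20 and rose in 2 (Cxcr4 -1.62, Ccr2 -1.47; adjusted p = 0.182, 0.251 and 0.346 with an estimated correlation). Proteasome genes rose in 19 of 20 (Psma7 0.52), oxidative phosphorylation genes in 19 of 33 (Cox5a 0.70), genes of the unfolded protein response and secretion in 14 of 23 with 1 falling (Trib3 2.32, Canx 0.36), and glycolysis genes in 8 of 16 with 1 falling (Tpi1 0.95; adjusted p = 0.296, 0.464, 0.498 and 0.365 with an estimated correlation). Camera called no change of lipid genes (8 of 20 up, 2 down; Fabp5 1.27, Dgat2 -2.56), inflammatory ILC2 genes (1 of 12 up, 3 down; Rorc -1.02, Ly6c2 -2.57), activation receptors (7 of 20 up, 9 down; Lag3 2.93, Cd6 -2.07) or interferon response genes (6 of 26 up, 4 down; Mx1 2.40, Slfn5 -1.05; adjusted p = 0.344, 0.344, 0.397 and 0.628). For activation receptors the median (-0.05) had the opposite sign to the test.

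EdgeR called 6136 genes between NMU+IL-25 and IL-25, 3161 up and 2975 down, and 4248 to 5046 with any single library left out. Markers of other lymphocytes fell as well: 7 of 9 ILC3, 8 of 12 ILC1 or NK, 4 of 7 T cell and 7 of 11 ILC2 markers fell, and 1 ILC1 or NK marker rose.

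The interaction of NMU and IL-25 asked whether the joint change differed from the sum of the separate changes on the log2 scale. Csf2 stood at 182.8 CPM after PBS, 236.2 after NMU, 278.9 after IL-25 and 15.8 after both, so that its interaction was -4.51 (adjusted p = 0.000501). The triglyceride gene Dgat2 stood at 7.69, 23.3, 253.8 and 42.9 CPM in the same order (interaction -4.16, adjusted p = 9.4e-05). Cpa3 (-3.35), Cxcl1 (-3.06), the serotonin synthesis gene Tph1 (-2.91), Bmp2 (-2.81), Csf1 (-2.75) and Ccl1 (-2.52) also fell below the sum (largest adjusted p = 0.00124). Igfbp4 lay above it by 2.07, Slc7a5, which encodes an amino acid transporter, by 1.79, Adk by 1.75, Galk1, Tmem97 and Ybx3 by 1.62, Mettl1 by 1.61 and Gsto1 by 1.60 (largest adjusted p = 0.0199). The type 2 cytokine genes lay below the sum, Il5 by -1.5, Il13 by -1.12 and Areg by -1.45 (adjusted p = 0.0225, 0.0285 and 0.00256), as did Il1rl1 (-0.64) and Gata3 (-0.47; adjusted p = 0.0234 and 0.00897), while Il17rb lay above it by 0.68 (adjusted p = 0.00596). The call of Il13 was lost without either PBS library, the second IL-25 or the first NMU+IL-25 library (adjusted p = 0.0649 to 0.0842), and that of Il5 without these or the first IL-25 library (0.0529 to 0.0709). That of Il1rl1 was lost without the first PBS, the first IL-25, either NMU or the second NMU+IL-25 library (0.0526 to 0.0885). Nmur1 (-0.82), Klrg1 (-0.49), Calca (-0.62) and Mki67 (-0.09) were not called (adjusted p = 0.0912, 0.0912, 0.0917 and 0.794).

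Of immediate early genes 12 of 23 lay below the sum and none above (Klf4 -1.61, Nr4a1 -1.53), and of the receptor list 8 of 12 (Vipr2 -0.96, Ramp1 -0.86; adjusted p = 0.0502 for each with an estimated correlation). Ribosome biogenesis genes lay above it in 24 of 25 (Ppan 1.10, Fbl 0.94; adjusted p = 0.0846 with an estimated correlation) and S phase genes in 25 of 42 (Chaf1b 1.62, Tipin 1.32). Type 2 cytokines lay below in 8 of 16 (Il2 -2.38), NF-kB targets below in 11 of 18 and above in 1 (Bcl2a1b -1.77, Nfkb1 0.60), and activation receptors below in 8 of 20 and above in 3 (Tnfrsf9 -1.53, Pdcd1 -1.13, Il2ra 0.60); with S phase, adjusted p = 0.164 for each with an estimated correlation. ILC2 identity genes lay below in 10 of 15 and above in 2 (Il7r -1.13, Ets1 -0.81), glycolysis genes above in 8 of 16 (Ldha 0.56), proteasome genes above in 15 of 20 (Psmb4 0.61) and oxidative phosphorylation genes above in 21 of 33 and below in 1 (Cyc1 0.79; adjusted p = 0.280, 0.268, 0.268 and 0.286 with an estimated correlation). G2/M phase genes lay above in 13 of 52 (Kif23 1.54, Tubb4b 1.05), genes of the unfolded protein response and secretion above in 10 of 23 (Trib3 3.70) and trafficking receptors below in 7 of 20 and above in 1 (Itgae -2.10, Ccr7 3.08; adjusted p = 0.341, 0.351 and 0.341 with an estimated correlation). Camera called no interaction of inflammatory ILC2 genes (1 of 12 above, 4 below; Irf4 -1.57), lipid genes (4 of 20 above, 2 below; Fasn 1.23) or interferon response genes (1 of 26 above, 5 below; Bst2 0.87, Gbp2 -0.85; adjusted p = 0.165, 0.213 and 0.907). The mean of lipid genes (-0.02) had the opposite sign to their median (0.37).

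The interaction was called for 3289 genes, 1653 above the sum and 1636 below. Cell type markers lay below it too, in 8 of 12 for ILC1 or NK cells, 5 of 9 for ILC3s, 4 of 7 for T cells and 7 of 11 for ILC2s, with 1 ILC2 and 1 of 13 macrophage, monocyte or dendritic cell markers above. Without the first IL-25 library the count was 2181 and without the first NMU+IL-25 library 2157. Scaled by library totals alone, 28% of called genes lay above the sum against 50.3%, and the median interaction of all tested genes was -0.22 against -0.06.

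Shares of single cells were counted at equal depth, 1000 UMIs per cell, to ask whether more cells carried these transcripts. Cells with an Il13 UMI made up 1.5% ± 0.157 after PBS, 2.78% ± 0.899 after NMU, 23.2% ± 4.69 after IL-25, 34.2% ± 1.31 after IL-33 and 34.4% ± 3.75 after NMU+IL-25 (SD, n = 2). Shares with an Il5 UMI were 3.92% ± 0.141, 8.46% ± 3.08, 14% ± 1.58, 15.8% ± 1.5 and 15.8% ± 0.942 in the same order. Areg was found in 11.6% ± 1.36, 11.3% ± 1.89, 20.1% ± 1.81, 10.5% ± 0.879 and 9.47% ± 0.368 of cells in that order. Il17rb was found in 2.45% to 4.08% of cells per group. Its background in ILC1 or NK-like cells ran from 0% after PBS to 4.26% (2 of 47) after IL-33, against 2.89% and 4.04% of ILC2-like cells. Cycling cells made up 25.2% ± 2.41 after PBS, 27.5% ± 3.56 after NMU, 32.5% ± 4.01 after IL-25, 68.9% ± 1.08 after IL-33 and 61.5% ± 0.313 after NMU+IL-25. By the stricter mitotic measure the shares were 0.256% ± 0.022, 0.633% ± 0.212, 4.19% ± 0.997, 17.5% ± 0.926 and 15.9% ± 0.277. Without thinning, Il13 was found in 3.24%, 7.49%, 49.8%, 85.7% and 80.6% of cells, Il5 in 9.65%, 23.2%, 41.7%, 69.2% and 59.3%, Areg in 21.9%, 23.2%, 42.3%, 40.5% and 32.6%, and cycle genes in 77.8%, 83.9%, 95.2%, 99.7% and 99.6%. The share with Areg thus lay above PBS after IL-33 and NMU+IL-25 without thinning and below it at equal depth.

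ILC1 or NK-like cells, which should lack Il13, gave its background: 0 of 140 cells after PBS, 4 of 76 (5.26%) after IL-25 at a median of 3990 UMIs, where ILC2-like cells held 19.9% at 4419 UMIs, and 7 of 47 (14.9%) after IL-33 at 6347 UMIs, where ILC2-like cells held 35% at 13046 UMIs. After NMU+IL-25 it was 2 of 32 (6.25%) against 32.3%. After IL-25, 8 of 35 endothelial-like cells (22.9%) also held an Il13 UMI. For Il5 the background was 1 of 140 ILC1 or NK-like cells after PBS (0.714%), 1 of 76 after IL-25 (1.32%), 3 of 47 after IL-33 (6.38%) and 3 of 32 after NMU+IL-25 (9.38%), where ILC2-like cells held 4.22%, 15.5%, 16.8% and 17.1%. After IL-25, 5 of 35 endothelial-like cells (14.3%) held an Il5 UMI. For Areg, ILC1 or NK-like cells held 2.86% after PBS, 4.21% after NMU, 6.58% after IL-25, 2.13% after IL-33 and 0% after NMU+IL-25, against 12.5%, 12%, 22.7%, 10.1% and 9.14% of ILC2-like cells. Background was not subtracted from the shares. Cells under 1000 UMIs, left out of the shares, numbered 64 after PBS (0.63%) and 0 in every other group. With 2 libraries per group the shares were not tested.

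**Figure D2:**
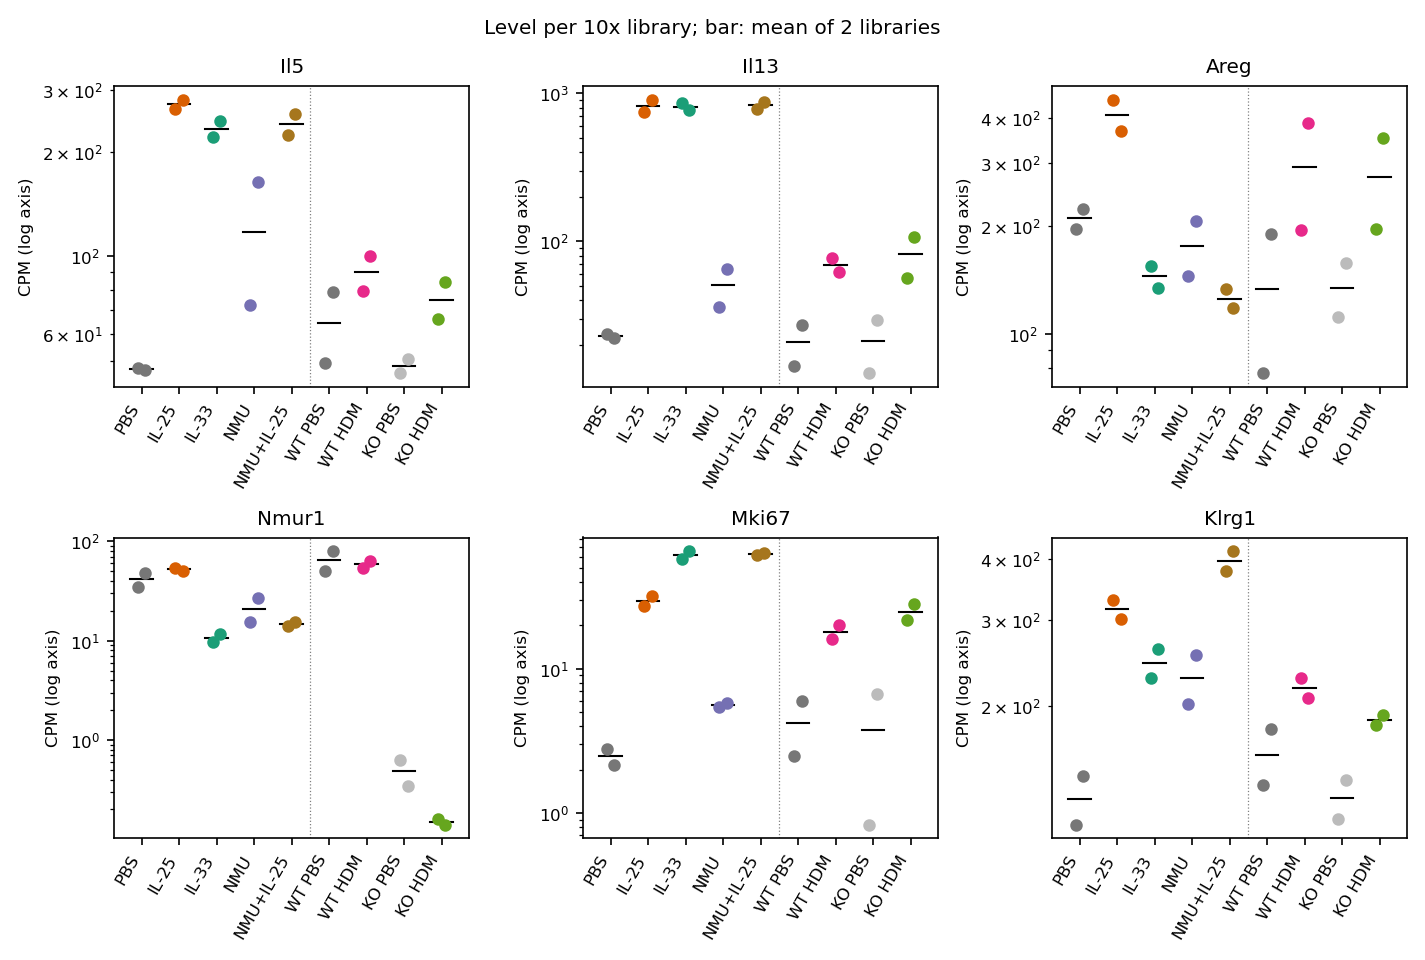
Levels of 6 genes in every droplet library, on a log axis. Il13 stood near 23 CPM after PBS and 824, 812 and 828 CPM after IL-25, IL-33 and NMU+IL-25.

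**Figure D3:**
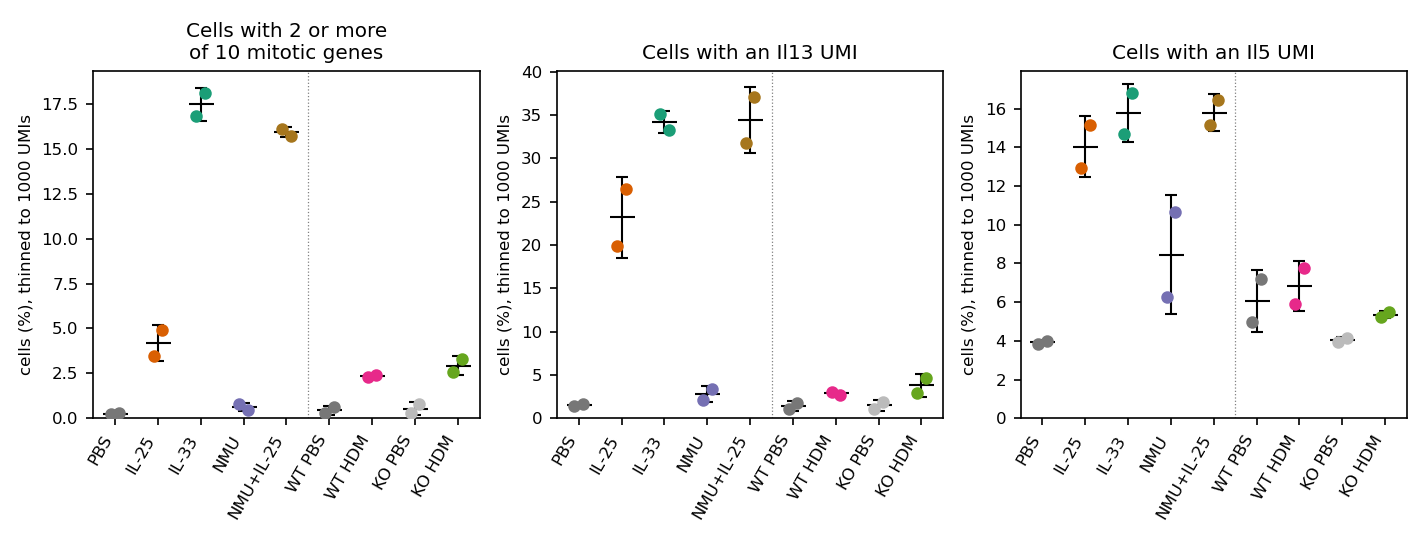
Shares of cells with mitotic transcripts, Il13 or Il5 after thinning to 1000 UMIs, with each library as a point and bars of mean and SD (n = 2). Mitotic cells ranged from 0.256% after PBS to 17.5% after IL-33.

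**Figure D4:**
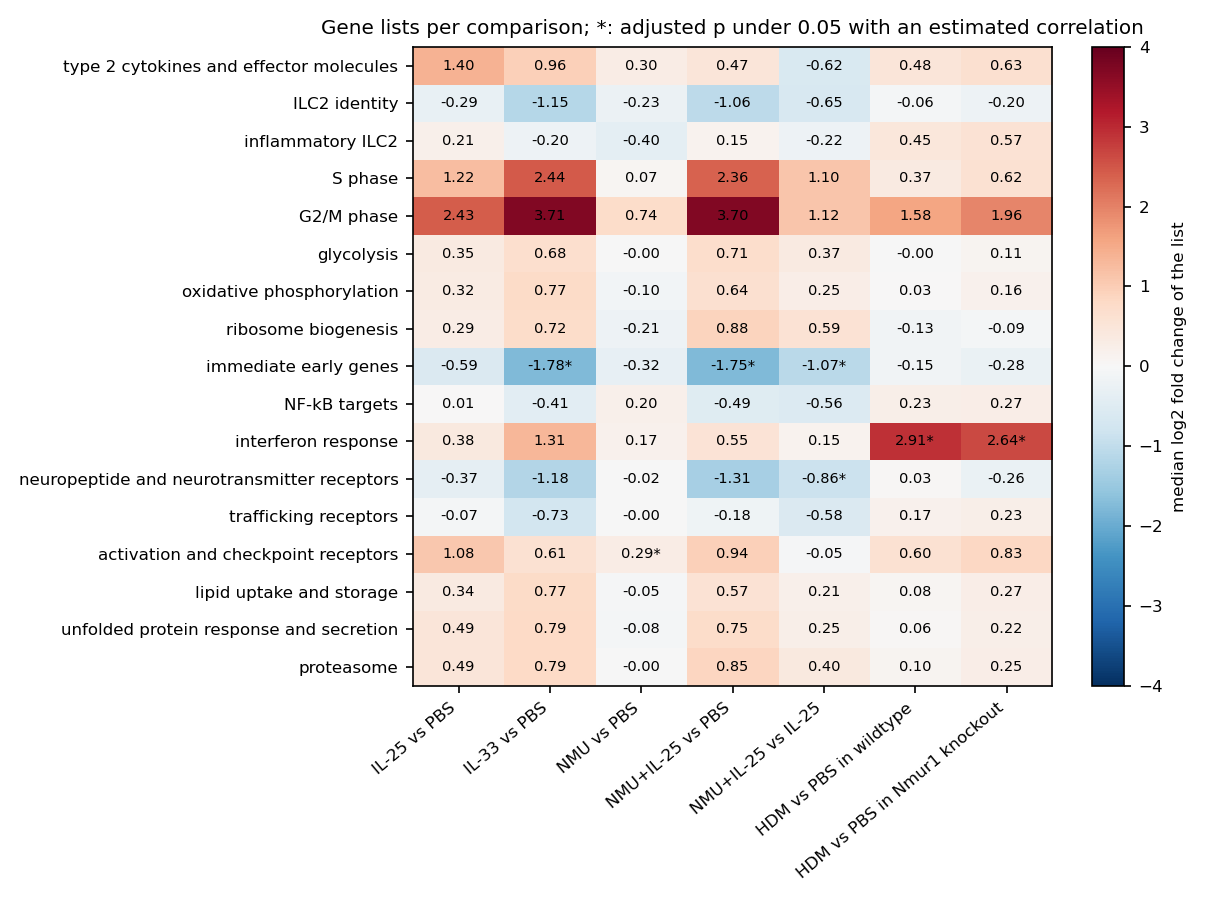
Median log2 fold change of each gene list in 7 comparisons, with a star where the adjusted p was under 0.05 with an estimated correlation. The largest medians were G2/M phase after IL-33 (3.71) and NMU+IL-25 (3.70).

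House dust mite extract was compared with PBS within each genotype, on days 0, 7, 8 and 9, to find the response to an allergen. In wildtype mice the interferon-inducible genes Ifit1 (log2 fold change 5.93), Ifit3 (5.63), Oasl2 (5.26), Iigp1 (4.78), Ifi27l2a (4.38), Usp18 (3.79) and Rtp4 (3.75) rose most, with Isg15 at 200.6 against 10.9 CPM (4.20; largest adjusted p = 0.000701). Mettl1 fell by 1.00 (adjusted p = 0.00523) and was the falling gene that the naming rule admitted. Interferon response genes rose in 25 of 26, with Irf7 at 2.92 and Irf9 at 2.10 (median 2.91), and the list's call was kept (adjusted p = 0.0213 with an estimated correlation). Il13 (1.75), Il5 (0.48), Areg (1.12), Mki67 (2.12), Klrg1 (0.46), Nmur1 (-0.14), Il17rb (-0.00), Il1rl1 (-0.17), Gata3 (-0.16) and Calca (0.28) were not called in wildtype mice by the fit without pairing of libraries (smallest adjusted p = 0.0859), which does not show that they were unchanged. For Il13, Il5, Areg and Mki67 the call depended on whether libraries of equal number were treated as pairs, which the labels do not state.

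G2/M phase genes rose in 26 of 52 after HDM in wildtype mice (Hmmr 2.75, Psrc1 2.34, Cdca8 2.02), S phase genes in 2 of 42 (Gins2 1.47, Tyms 1.09), and activation receptors in 5 of 20 with 1 falling (Lag3 3.65, Ly6a 2.51, Cd274 1.52, Il2rb 0.87; adjusted p = 0.218, 0.427 and 0.0947 with an estimated correlation). NF-kB targets rose in 3 of 18 and fell in 1 (Traf1 0.67, Nfkbie 0.66, Bcl2l1 -0.83), and inflammatory ILC2 genes rose in 2 of 12 (Ly6c2 2.60, whose reads may be shared with its paralog Ly6c1, and Batf 0.54; adjusted p = 0.363 and 0.323 with an estimated correlation). Camera also called type 2 cytokines up and ribosome biogenesis down with 0 members called (adjusted p = 0.00712 and 0.0013), and these calls were lost (adjusted p = 0.509 and 0.323 with an estimated correlation). No other list was called in wildtype mice. ILC2 identity genes rose in 1 of 15 and fell in 1 (Crlf2 0.46, Il2ra -0.60). In the receptor list 1 of 12 rose (Ptger2 0.72), and of secretion genes 1 of 23 (Ssr3 0.55). No member of glycolysis, oxidative phosphorylation, immediate early, trafficking, lipid or proteasome lists was called. The median of ILC2 identity genes (-0.06) had the opposite sign to their mean (0.0018).

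EdgeR called 392 of 12674 genes (3.09%) in wildtype mice, 89.8% of them up. With a library left out, and the lone library assumed to vary like the others, the share called was 1.07% without the first wildtype PBS library, 1.44% without the second, 1.47% without the first HDM library and 1.51% without the second. Beside these, 5 of 13 macrophage, monocyte or dendritic cell markers and 1 of 14 ILC1 or NK markers rose.

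In Nmur1 knockout mice HDM raised Ifit1 by 5.2 and Iigp1 by 4.49 on the log2 scale (adjusted p = 0.000778 and 0.00076). Several of the largest rises were of genes highest in macrophage-like or, for Retnla, endothelial-like cells. Retnla rose at least 391-fold from 0 UMIs, Ccl24 from 0.0248 to 52.9 CPM, Chil3 by 4.51, and the MHC class II genes H2-Eb1 and H2-Ab1 by 4.17 and 4.12 (largest adjusted p = 0.0219). Gzmb rose by 4.94 (adjusted p = 0.00964). Hba-a1 (-1.85), Hist1h2bc (-1.63), Klf9 (-1.37), Tmppe (-1.23), Stc2 (-1.19), Lpcat2 (-1.18) and Pard3 (-1.16) fell (largest adjusted p = 0.0288), and Hba-a1 reads could not be told from its copy. Il13 rose by 1.84 (21.3 to 81.7 CPM, adjusted p = 0.0446) and Mki67 by 2.38 (adjusted p = 0.0394). Without the first knockout PBS or the second knockout HDM library both calls were lost (adjusted p = 0.188 and 0.211 for Il13, 0.106 and 0.162 for Mki67), as was Il13 without the second PBS library (0.0789) and Mki67 without the first HDM library (0.0539). Il5 (0.63), Areg (1.02), Klrg1 (0.53), Il17rb (0.09), Il1rl1 (-0.38), Gata3 (-0.42), Calca (0.09) and Nmur1 (-1.39) were not called in knockout mice by the same fit (smallest adjusted p = 0.0557), and the calls of Il5, Areg, Klrg1 and Il1rl1 depended on pairing in the same way.

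Interferon response genes rose in 25 of 26 after HDM in knockout mice as well (Rtp4 3.18, Irf7 2.54; adjusted p = 0.0439 with an estimated correlation). G2/M phase genes rose in 35 of 52 (Hmmr 3.07, Aurka 2.47), S phase genes in 15 of 42 (Gins2 1.59, Hells 1.04), and activation receptors in 8 of 20 with 2 falling (Ly6a 2.79, Il2rb 0.98, Il2ra -0.74; adjusted p = 0.147, 0.278 and 0.147 with an estimated correlation). NF-kB targets rose in 5 of 18 and fell in 1 (Bcl2a1b 1.35, Bcl3 1.07, Bcl2l1 -0.96), proteasome genes rose in 3 of 20 (Psma4 0.52), oxidative phosphorylation genes in 3 of 33 (Cycs 0.48) and secretion genes in 1 of 23 (Ssr3 0.50), and immediate early genes fell in 2 of 23 (Hspa1b -1.79, Ier2 -0.53). Camera called these 5 lists, and the calls were lost (adjusted p = 0.538 for each with an estimated correlation). Inflammatory ILC2 genes rose in 1 of 12 (Batf 0.61; adjusted p = 0.278 with an estimated correlation). No other list was called. Type 2 cytokines rose in 2 of 15 and fell in 1 (Penk 5.99, Il2 -0.92). ILC2 identity genes rose in 2 of 15 and fell in 2 (Tcf7 0.78, Hs3st1 -0.50). Lipid genes rose in 2 of 20 (Fabp5 2.32, Dgat1 1.15). Of the receptor list 1 of 12 rose (Ptger2 1.07), 1 of 20 trafficking receptors fell (Ccr2 -0.47), and no glycolysis or ribosome biogenesis gene was called.

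EdgeR called 1095 genes (8.64%) in knockout mice, 69.5% of them up, or 55.5% when libraries were scaled by totals alone. The share called was 1.40% without the first knockout PBS library, which held the fewest UMIs, 1.71% without the second and 1.86% without the second knockout HDM library, against 8.40% without the first. Markers of other cells rose too: 12 of 13 macrophage, monocyte or dendritic cell, 4 of 8 T cell and 3 of 14 ILC1 or NK markers.

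Of 392 genes called after HDM in wildtype mice, 99.5% had the same sign in the knockout (Pearson r = 0.902, slope 0.944). Of 1095 called in the knockout, 99.4% had the same sign in wildtype mice, where they changed less (slope 0.673; median absolute log2 fold change 0.63 against 0.88). Genes picked by their call in one genotype are expected to look weaker in the other. In all, 25 falling genes were called in both where 1.1 were due if the calls were independent. Fibin, chosen after the values were seen, was called in both with opposite signs (-3.11 and 3.32), at no more than 2.44 CPM in any group. Cells with an Il13 UMI made up 1.41% ± 0.549 after PBS and 2.88% ± 0.248 after HDM in wildtype mice, and 1.48% ± 0.632 and 3.79% ± 1.29 in knockout mice (SD, n = 2; unthinned 4.91%, 8.78%, 4.31% and 11.2%). Il5 was found in 6.08%, 6.83%, 4.06% and 5.35% of cells in the same order and Areg in 8.46%, 14.8%, 8.13% and 13.7% (unthinned 20.3%, 23.7%, 14.2% and 19.3%, and 21.6%, 32.9%, 19.7% and 30.3%). After HDM, ILC1 or NK-like cells held Il13 in 1.06% (wildtype, median 5164 UMIs) and 1.12% (knockout, 5332 UMIs) of cells, against 2.72% and 4.22% of ILC2-like cells at 3927 and 4036 UMIs. They held Il5 in 2.11% and 1.31% against 7.6% and 6.86%, and Areg in 6.69% and 3% against 16.9% and 17.8%. Mitotic cells made up 0.442% ± 0.237 and 2.34% ± 0.091 in wildtype and 0.530% ± 0.349 and 2.93% ± 0.538 in knockout mice. The broader cycling share lay lower after HDM (28.6%, 26.6%, 30.6% and 28.3%). No cell of this set was under 1000 UMIs, and the shares were not tested.

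**Figure D5:**
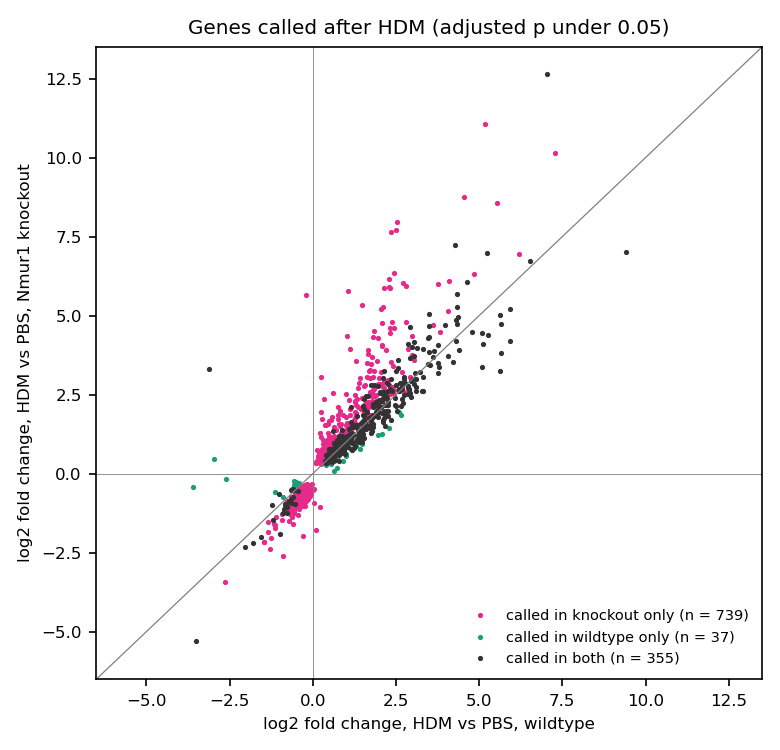
Log2 fold changes after HDM in wildtype and knockout mice for genes called in either. Among them 739 were called in the knockout only.

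Loss of Nmur1 was compared with wildtype after PBS and after HDM. Nmur1 itself stood at 50.6 and 79.6 CPM in wildtype PBS libraries, 53.7 and 64.1 in wildtype HDM, 0.62 and 0.35 in knockout PBS (3 and 7 UMIs) and 0.16 and 0.14 in knockout HDM (3 and 3 UMIs). It fell by 7.30 after PBS and 8.55 after HDM on the log2 scale (adjusted p = 0.000652 and 0.000231). The labels do not say which part of the gene was deleted, and a 3' tag cannot show whether a protein was made. Pydc3, an interferon-inducible gene of the pyrin family chosen after the values were seen, fell from 12.7 to 2.22 CPM after PBS and from 31.9 to 4.11 CPM after HDM (-2.74 and -2.95; adjusted p = 0.0411 and 0.00699), and its reads may be shared with close paralogs. The Pydc3 call after PBS was lost without either wildtype library or the second knockout library (adjusted p = 0.129, 0.079 and 0.737), and that after HDM without either wildtype library or the second knockout library (0.0657, 0.0916 and 0.1). The log2 fold change of Pydc3 ran from -2.11 to -3.08 in these fits. The call after PBS was also lost with library totals alone and with thinned totals (adjusted p = 0.0528 and 0.196), whereas within ILC2-like clusters alone Pydc3 fell by 4.54 after PBS and 4.56 after HDM (adjusted p = 0.00206 and 0.000166). The relaxin family gene Rln3 fell by 1.51 after PBS (adjusted p = 0.0373) and was not called after HDM (-0.43, adjusted p = 0.552). Without the second knockout PBS library neither Nmur1 (-6.68) nor Rln3 was called after PBS (adjusted p = 0.107 and 0.209), nor was Rln3 without either wildtype PBS library (0.129 and 0.166).

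Il5 (-0.40 after PBS, -0.26 after HDM), Il13 (0.14 and 0.23), Areg (0.02 and -0.09), Klrg1 (-0.29 and -0.22), Il17rb (-0.05 and 0.04), Il1rl1 (-0.06 and -0.27), Gata3 (-0.07 and -0.33), Calca (0.44 and 0.24) and Mki67 (0.20 and 0.46) were not called between genotypes (smallest adjusted p = 0.577). No marker of any cell type was called in either comparison, and no member of any list but Nmur1. The receptor list fell after PBS (camera adjusted p = 0.000216; adjusted p = 0.171 with an estimated correlation) and after HDM (adjusted p = 0.0399 with an estimated correlation), but without Nmur1 neither camera call remained (adjusted p = 0.999 and 0.0629). No other list was called after PBS (smallest camera adjusted p = 0.349).

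After HDM, camera called G2/M phase (median 0.33), S phase (0.28), inflammatory ILC2 (0.52), secretion (0.16), oxidative phosphorylation (0.11), proteasome (0.09) and ribosome biogenesis genes (0.06) higher and interferon response genes (-0.25) lower in the knockout, with 0 members called in each. All 8 calls were lost (smallest adjusted p = 0.621 with an estimated correlation). The direction turned for secretion and proteasome genes without the second knockout HDM library (camera adjusted p = 0.718 for each) and for interferon response genes without the second wildtype HDM library (0.0707). Type 2 cytokines (median 0.07, Il5 -0.26), ILC2 identity (-0.09), glycolysis (0.02), immediate early genes (-0.10), NF-kB targets (-0.04), trafficking receptors (0.06), activation receptors (0.15) and lipid genes (-0.06) were not called after HDM (smallest camera adjusted p = 0.117). For type 2 cytokines the test pointed down against a positive median and mean, and for lipid, NF-kB and immediate early genes the mean was positive (0.20, 0.04 and 0.0028). After PBS median and mean differed in sign for type 2 cytokines (0.0089 and -0.32), ILC2 identity, trafficking and activation genes.

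Between genotypes edgeR called 3 of 12674 genes after PBS (0.0237%) and 2 after HDM (0.0158%), all lower in the knockout. DESeq2 called 23 and 41. Leaving out a library gave 1 gene without either wildtype PBS library, 0 without the second knockout PBS library, 1 without either wildtype HDM library, 33 without the first knockout HDM library and 1 without the second, with the lone library assumed to vary like the others.

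The interaction of genotype and HDM asked whether Nmur1 shaped the response to HDM. Il13 (0.10), Il5 (0.14), Areg (-0.10), Klrg1 (0.07), Il17rb (0.09), Il1rl1 (-0.21), Gata3 (-0.26), Calca (-0.19), Mki67 (0.26) and Nmur1 (-1.25) gave no interaction. EdgeR called 0 genes, with 2.75% of tested genes at an unadjusted p under 0.05, and DESeq2 called 1. With the first knockout HDM library left out edgeR called 2 genes. Camera called S phase (median 0.26), G2/M phase (0.21), secretion (0.17), proteasome (0.17), oxidative phosphorylation (0.13) and ribosome biogenesis genes (0.08) as responding more in the knockout, and interferon response genes (-0.34), neuropeptide receptors (-0.17), ILC2 identity (-0.13) and immediate early genes (-0.11) as responding less, with 0 members called. Without Nmur1 the call of neuropeptide receptors was lost (camera adjusted p = 0.0837). All 10 calls were lost (smallest adjusted p = 0.635 with an estimated correlation). The direction turned for interferon response genes without the second wildtype HDM library, for immediate early genes without the first wildtype PBS library, for G2/M phase genes without the first knockout PBS library and for ILC2 identity genes within ILC2-like clusters alone (camera adjusted p = 0.537, 0.331, 0.847 and 0.681). Type 2 cytokines, inflammatory ILC2, glycolysis, NF-kB, trafficking, activation and lipid lists were not called (smallest camera adjusted p = 0.177), and type 2 cytokines had a median of -0.05 against a mean of 0.48. In simulated data this interaction found 14.3% of 2-fold changes, so that smaller effects of the genotype would have been missed.

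SMART-Seq2 plates asked whether full-length data gave the same responses to IL-25 and IL-33. After IL-25 Il5 rose by 2.68 on the log2 scale, the IL-1 pathway gene Irak3 by 2.65, and the mitotic genes Cdca8 and Ncaph stood at 46.4 and 42.2 CPM against 0.0407 and 0.0053 CPM (largest adjusted p = 0.0381). Il1r2, chosen after the values were seen, had 0 counts after PBS and 17.7 CPM after IL-25 (adjusted p = 0.022). After IL-33 Il1r2 rose from 0 counts after PBS to 372.6 CPM. Cdc6 (83.8 CPM), Fignl1 (67.9), Chaf1a (57.8), Cdca3 (51.8), Zbtb32 (49.2), Ckap2l (46.8) and Slc1a4 (42.7) also rose from 0 counts (largest adjusted p = 0.0357). No floor of the fold is given for these, because plate counts are reads without UMIs and do not count transcripts. Il5 rose by 2.67 and Uhrf1 by 5.28 (adjusted p = 0.0239 and 0.0131), and Lpcat2 (-3.22), Sema4a (-2.49), Inpp4b (-2.02), Junb (-1.99) and Ppp1r15a (-1.67) fell (largest adjusted p = 0.0378). The Il5 calls were lost without the second PBS replicate (adjusted p = 0.105 after IL-25 and 0.066 after IL-33), either IL-25 replicate (0.0822 and 0.0583) or either IL-33 replicate (0.0898 and 0.0874). Irak3 was lost without the second PBS or either IL-25 replicate (0.0583 to 0.106).

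On plates Nmur1 (1.16 after IL-25, -0.89 after IL-33), Il13 (4.15 and 4.89), Areg (1.80 and -0.02), Il17rb (0.10 and 1.19), Il1rl1 (0.34 and -0.46), Klrg1 (1.3 and 0.98), Gata3 (-0.11 and -1), Calca (1.3 and 0.68) and Mki67 (3.92 and 5.90) were not called (smallest adjusted p = 0.101). After IL-25 1 of 52 G2/M phase and 1 of 13 type 2 cytokine genes rose, and camera also called S phase, oxidative phosphorylation, activation, lipid and proteasome genes up with 0 members called. All 7 calls were lost (smallest adjusted p = 0.122 with an estimated correlation), and the remaining 10 lists were not called (smallest camera adjusted p = 0.0866). After IL-33 5 of 42 S phase genes (Mcm5 2.91, Mcm6 2.48), 5 of 52 G2/M phase genes (Cdk1 7.94) and 1 of 13 type 2 cytokine genes rose and 1 of 23 immediate early genes fell. Camera called the first 3 lists, inflammatory ILC2, glycolysis, oxidative phosphorylation, interferon response, activation, lipid, secretion and proteasome genes up, and immediate early, ILC2 identity and neuropeptide receptor genes down. All 14 calls were lost (smallest adjusted p = 0.0759 with an estimated correlation), and NF-kB targets, trafficking receptors and ribosome biogenesis genes were not called (smallest camera adjusted p = 0.0522). Median and mean differed in sign for ILC2 identity, inflammatory ILC2, immediate early and secretion genes after IL-25 and for NF-kB targets after IL-33.

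EdgeR called 5 of 13117 genes (0.0381%) after IL-25, all up, and 37 (0.282%) after IL-33, 32 up and 5 down. Without the first PBS replicate the shares were 0.511% and 1.3%, without the first IL-25 replicate 0.0152%, without the second PBS replicate 0.0915% after IL-33, and 0.0152% without either IL-33 replicate. DESeq2 called 687 and 1032 genes, but 78.4% of its calls in simulated plate data were false. Scaled by totals alone, 75.6% of the genes called after IL-33 were up against 86.5%, and the median log2 fold change was -0.20 against -0.05. Among ILC2 markers 1 of 11 rose in each comparison and no other cell type's marker was called.

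Effects on both platforms were then compared gene by gene. Of 4170 genes called after IL-25 in droplets and measured on plates, 2900 (69.5%) had the same sign (Pearson r = 0.489), and of 7790 after IL-33, 6276 (80.6%; r = 0.661). Among droplet genes with an absolute log2 fold change of at least 1 the shares were 78% and 87.3%. All 5 and all 37 genes called on plates had the same sign in droplets. Cells of both platforms came from the same treatments, but the labels do not say whether they came from the same mice.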

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

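The ratio of called genes at thinned totals was a test chosen after the result was seen, and the other settings named in this part were planned.

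The effect of NMU differed between mice given IL-25 and mice not given it, by a test of the difference itself, in 3289 of 13205 genes. Csf2 gave a difference of -4.51: it stood at 236.2 CPM after NMU against 182.8 after PBS, but at 15.8 CPM after NMU+IL-25 against 278.9 after IL-25. Igfbp4 gave 2.07: NMU lowered it from 55.8 to 22.9 CPM, whereas with IL-25 it stood at 22.8 against 13.2 CPM. Without the first NMU+IL-25 library 16.3% of genes were called and without the first IL-25 library 16.5%, against 24.9% with all 8 libraries.

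More UMIs in the NMU+IL-25 libraries were weighed first as the cause of the larger number of genes called there than after IL-25. With every library thinned to the smallest total, NMU+IL-25 still gave 1.96 times as many called genes against PBS as IL-25 did (1.95 times without thinning), and the difference in the NMU effect was called for 20.1% of genes. These values argue against depth as the whole cause. Cells outside ILC2-like clusters may add to it, but within ILC2-like clusters 26.5% of genes were called, so they were not needed for most of the count. No label gave a library batch, and 2 libraries per group leave open a difference between the pools.

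A candidate explanation for the cytokine genes is a ceiling. Il13 stood at 828 CPM after NMU+IL-25 and 824 after IL-25, so that the negative difference of -1.12 could arise if NMU had no room to raise this mean level further. It was -1.13 with thinned totals (adjusted p = 0.0271), and its call was lost without either PBS library, the second IL-25 library or the first NMU+IL-25 library (adjusted p = 0.0649 to 0.0842). A ceiling does not explain Csf2, Dgat2 or Areg, which stood lower after NMU+IL-25 than after IL-25. For these genes an opposing effect of NMU in the presence of IL-25 is a hypothesis that the same 8 libraries raised and cannot test.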

How the results depend on the processing

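The mitotic measure, the fits without clusters of other cell types and the receptor list without Nmur1 were chosen after seeing the data, and the other settings were planned. Counts of called genes are given as percent of the genes tested with the settings of the report. Replicate numbers gave no stated pairing, so the replicate block was run as an alternative; libraries of equal number deviated together with correlations of -0.264 to 0.493 in the 3-day set, 0.188 to 0.592 in the HDM set and -0.034 to 0.238 on plates. With the replicate block 6.18% of genes were called for HDM in wildtype and 15.7% in knockout mice (against 3.09% and 8.64%), 0.0473% and 0.0316% for knockout against wildtype after PBS and HDM (0.0237% and 0.0158%), and 0.0152% and 0.061% on plates after IL-25 and IL-33 (0.0381% and 0.282%). The block also called genes after HDM that the unpaired fit did not: Il13, Areg, Mki67 and Il5 in wildtype mice (1.85, 1.16, 2.17 and 0.50 on the log2 scale; adjusted p = 0.00998, 0.00396, 0.00921 and 0.0431) and Areg, Il5, Klrg1 and Il1rl1 in knockout mice (0.99, 0.64, 0.53 and -0.38; adjusted p = 0.00633, 0.0124, 0.025 and 0.0214). Without an expression filter the shares were 7.3% for NMU (4.13%), 6.59% and 14.1% for HDM, 0.26% and 0.939% for the genotype, 0.0631% for genotype by HDM (0%), and 0.793% and 2.53% on plates. DESeq2 called 0.181% and 0.323% for the genotype, 0.00789% for genotype by HDM, and 5.24% and 7.87% on plates. Library totals gave 6.33% for NMU and 0.00789% for the genotype after PBS, as did thinned totals for the latter. Limma on plate TPM gave 0.686% for IL-33 (pseudocount 1) and 0.0229% for IL-25 (0.1).

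With 1 library left out, and the lone library assumed to vary like the others, the lowest and highest shares were 22.6% and 29.9% for IL-25 (34.4%), 0.795% and 2.11% for NMU, 16.3% and 22.1% for NMU by IL-25 (24.9%), 1.07% and 1.51% for HDM in wildtype, 1.4% and 8.4% in knockout, 0% and 0.0316% for the genotype after PBS, 0.00789% and 0.26% after HDM, 0% and 0.0158% for genotype by HDM, and 0.0152% and 0.511% (IL-25) and 0.0152% and 1.3% (IL-33) on plates. In all, 52 alternative counts moved by more than 1.5 times.

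Ly6c2 changed sign within ILC2-like clusters and with other cell types left out, after IL-25 (0.90 and 0.86) and IL-33 (0.97 and 0.98), and so did Ccr7 after NMU (0.56 and 0.71). Of 14216 gene results, 13345 kept direction and call, 462 lost the call, 403 gained it and 6 reversed. With an estimated correlation 3.62% of list tests were called, against 61.5% by camera and 45.2% by fry. The direction of a list test turned with a single library left out in 8 cases, whose adjusted p ran over these ranges: for knockout against wildtype after PBS, G2/M phase genes (4.64e-08 to 0.319, turned without the second knockout PBS library); after HDM, interferon genes (1.1e-23 to 0.0707, second wildtype HDM library), lipid genes (0.0207 to 0.923, first knockout HDM library), secretion genes (3.28e-05 to 0.718) and proteasome genes (0.00226 to 0.795, both second knockout HDM library); and for genotype by HDM, immediate early genes (1.35e-12 to 0.953, first wildtype PBS library), interferon genes (8.59e-20 to 0.537, second wildtype HDM library) and G2/M phase genes (1.21e-18 to 0.847, first knockout PBS library). Within ILC2-like clusters it turned for type 2 cytokines between genotypes after HDM (0.0295) and ILC2 identity in genotype by HDM (0.681). Of 2946 list results 2751 kept direction and call.

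Shares of cells differed in sign with other settings for cycling cells after HDM in wildtype mice (1.90 points by mitotic genes), Areg after NMU+IL-25 (10.7 points above PBS without thinning), Il17rb after IL-25 (-0.122 points at 1500 UMIs, -0.264 within ILC2-like clusters) and Il17rb after HDM in knockout mice (-0.002 points at 1500 UMIs). Equal signs on plates rose to 78% (IL-25) and 87.3% (IL-33) among genes with an absolute log2 fold change of at least 1. The cause of these differences was not tested.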

Other observations

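All 7 tests of explanations in this part were chosen after the result was seen.

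MHC class II genes rose after HDM in wildtype mice too: H2-Eb1 by 3.06, H2-Aa by 2.99 and H2-Ab1 by 2.86 on the log2 scale (largest adjusted p = 0.0313). Within ILC2-like clusters the rises were 3.59, 3.48 and 3.15 (largest adjusted p = 0.00145). Cd74, which encodes the chaperone of MHC class II, stood at 29.9 CPM in ILC2-like cells of wildtype PBS mice and 258.6 CPM after HDM, and at 36.4 and 331.2 CPM in knockout mice. Cells of unnamed clusters held more, 1779 and 3849 CPM in wildtype mice. Levels in T cell-like cells of wildtype mice, which were not tested, stood higher after HDM as well, at 176.8 against 43.9 CPM for Cd74 and 29.5 against 3.77 CPM for H2-Aa, as RNA spread over every droplet would give.

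Genotype comparisons after PBS and after HDM share no library. At an unadjusted p under 0.01 in both, 35 genes besides Nmur1 moved one way, where chance gives 1.3. Wdfy1, whose gene lies 6.6 Mb from Nmur1, stood higher in the knockout by 1.18 and 1.17 on the log2 scale (adjusted p = 0.573 and 0.39), Il18r1, an IL-18 receptor gene, by 0.69 and 0.57, Slamf1 by 1.83 and 1.59, Tcf7 by 0.54 and 0.64, and Nnt by 0.56 and 0.51. None of these 5 genes was called in either comparison. The T cell genes Cd3e (1.00 and 1.26) and Cd3g (0.49 and 0.59) and Prdm1, a plasma cell marker, were among the 35, and the knockout libraries held more cells of other classes: 17.3% and 12.5% against 9.93% and 6.29% after PBS, and 25% and 35% against 19.1% and 11.4% after HDM.

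Variants carried with the deleted locus may play a part here. Wdfy1, Il18r1, Slamf1 and Pydc3 lie on chromosome 1, at 6.6, 45.9, 85.3 and 87.2 Mb from Nmur1. As the whole cause, through genes of chromosome 1 alone, linked variants were argued against by 31 genes on other chromosomes that moved one way. Of these, 3 were cell type markers. The count cannot exclude a linked variant that acts on genes elsewhere, because such genes would move too. Chromosome 1 held 4 of the 35 genes (11.4%) against 5.8% of other tested genes (1-sided exact p = 0.145), which leaves a part played by linked variants open. Strain variants elsewhere could lie scattered or in neighbouring genes. Gm16867 (-7.51 and -7.56), and Fgfbp3 and Ide on chromosome 19, stood lower. Of random draws, 56.3% held as many pairs within 1 Mb, too few to decide. Scattered variants were not tested and stay open. The larger share of other cells in the knockout was argued against as the whole cause, because within ILC2-like clusters alone 33 genes moved one way, where chance gives 1.0; 18 of the 35 were among them, and all 35 kept their sign. It may still be part of the cause for the T cell genes: Cd3e differed by 0.45 and 0.70 in ILC2-like cells, and RNA of T cells in those droplets was not removed. An effect of the lost receptor itself stays open. Crossing to one strain would remove unlinked variants only.

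Macrophage, monocyte or dendritic cell markers rose after HDM in the knockout, and cells of those types could have passed the sort, although its gate left out lineage-positive cells. Lyz2, Chil3 and H2-Ab1 stood at 2917, 2501 and 4238 CPM in macrophage-like and 6421, 4 and 448 in endothelial-like cells of knockout HDM libraries. With clusters of other cell types left out, the markers tested both ways kept 73.5% of their median log2 fold change (4.14 to 3.05), which decides neither way for the whole set. Of the 12 markers called, 4 dropped below the expression filter in that fit and are not among these 8, and the 5 markers outside MHC class II kept 58.3%. H2-Aa, H2-Ab1 and H2-Eb1, which B cells and activated lymphocytes also express, kept 89%, but unnamed clusters, at 1244 to 1441 CPM of H2-Aa and H2-Ab1, stayed in that fit. Within ILC2-like clusters alone, which leaves the unnamed clusters out too, all 3 genes still rose, by 3.28, 3.19 and 3.15 (largest adjusted p = 0.00344), so that cells counted in other clusters were not needed. Leaving cells out does not remove RNA they set free, however, and through it such cells could still be the whole source of the MHC class II rise. Free RNA in the droplets is a candidate source for the level in ILC2-like cells. This level was 0.93 times that in T cell-like cells of the same libraries (median of 8 markers, 0.64 to 1.45), as RNA spread over every droplet would give. Retnla and Ccl24 were examined after the values were seen. After HDM they stood at 5.82 and 4.85 CPM in ILC2-like, 423.2 and 983.7 in macrophage-like and 3093 and 0 in 46 endothelial-like cells. Sorting purified ILC2s again before HDM profiling would test whether any of the MHC class II rise is their own.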
